A study of Homo sapiens with 8 samples.

How the data were processed

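Gene expression was measured by RNA sequencing in EPC2-hTERT cells, a human esophageal keratinocyte line immortalized with telomerase and grown as a stratified epithelium at an air-liquid interface. Per the labels' protocols, cells were kept in defined keratinocyte medium with 50 µg/ml bovine pituitary extract and 1 ng/ml epidermal growth factor and were seeded on membranes with 0.4 µm pores. They grew to confluence over 2 days, spent 5 days in medium with 1.8 mM CaCl2 and were then exposed to air for 4 days. Cultures received DMSO vehicle or 1 mM dimethyloxalylglycine (DMOG) for 18 h before harvest. About 1 µg of total RNA per sample went into a library made with an NEBNext Ultra RNA kit. Groups were taken from the treatment named in the labels, and replicate numbers 1 to 4 from the sample titles. The labels do not say that replicates are separate cultures, so p-values measure only the spread between these samples, which may be technical.

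The authors deposited RPKM values (reads per kilobase of listed gene length, scaled to the library's total) for 25369 genes in all 8 libraries, although that table is named as raw counts. Per the submitters' processing notes, bcl2fastq, FastQC 0.11.5, TopHat2 2.0.13, Bowtie2 2.2.3.0, SAMtools 1.3.1, Picard 1.129 and HTSeq 0.6.1 were used. The notes give no role or order of these tools and name both GRCh37/hg19 and GRCh38/hg38. Chromosome and haplotype names in the RPKM table are those of hg19, and all positions given here are hg19 positions from that table, without exon detail. The handling of strand and of reads that map to several places is not given in the sources used here. Values of genes that overlap another gene, lie opposite an antisense gene or share sequence with pseudogenes, as ribosomal protein genes do, are therefore uncertain.

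Multiplying each RPKM by gene length and dividing by the value of 1 read gave whole reads. Of the values above 0, 100% were whole within 0.01 reads, and the largest deviation was 0.000331 reads. Library totals recovered in this way were 31245695 to 39931833 reads. One read was worth 0.0250 to 0.0320 RPM, so a gene listed at 0 could have up to 3 reads, or 0.0751 to 0.0960 RPM, by counting error alone. For 597 genes with several listed positions, the length was recovered from the values for 237, and the other 360 were at 0 in every library. Of the listed names, 28 had been turned into dates by a spreadsheet, and these genes are not named here. Mitochondrially encoded mRNAs and MUC5AC, which belonged to the gene lists, were not analysed here. Library pairs were compared by a chi-square statistic on recovered reads. It ranged from 20.7, for vehicle replicate 1 and DMOG replicate 2, to 410 per degree of freedom over the 28 pairs, with 36.4 for the most alike pair of vehicle libraries, so no library is a copy of another within sampling noise.

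The authors' deposited table of their own comparison gives, per the file headers, normalized group means on a signal scale, a ratio of the means, its log2 value, and a p-value with an adjusted p for 13424 genes. The tool behind that table is not given in the sources used here. Its group means were recovered from the reads to within a relative misfit of 8e-10 as means over vehicle replicates 1, 3 and 4 and DMOG replicates 1, 3 and 4. Replicate 2 of either group does not enter them, for a reason not given in the sources used here.

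The planned test was chosen before the data were examined and assumed raw counts, with limma-trend as the test for any other unit. As the table holds RPKM, limma-trend was used (limma 3.58.1, R 4.3.3, robust empirical Bayes) on log2(RPKM + 1) with the group as the only term. All 8 libraries entered, and genes with an RPKM of 1 or more in at least 4 libraries were tested (11122 genes). Tests were two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. Fold changes are on the log2(RPKM + 1) scale, DMOG minus vehicle, which understates the change of genes with low values. A second comparison was added after seeing the data, with the 6 libraries (3 per group) of the authors' own comparison. It is defined by their table. Their reason for leaving out replicate 2 is not given, so that choice may itself rest on the values measured in the libraries. The p-values of the 6-library comparison do not allow for such a choice. The RPKM of the 6 libraries were divided by median-ratio factors computed in base R, and the RPKM as deposited were fitted as an alternative. The filter remained that over all 8 libraries, so the same 11122 genes were tested. A gene at 1 RPKM or more only in DMOG replicates 1, 3 and 4 could not pass it. A gene at that level only in the 4 vehicle libraries could. Means with SD are RPKM as deposited.

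Whether replicate numbers pair the samples was checked by correlating the deviations from the group means of same-numbered libraries. Over the 6 libraries the correlations were 0.47, 0.40 and 0.34 for numbers 1, 3 and 4, and every library correlated best with its own number. With so few libraries per group such matches can arise without pairing, so whether the numbers pair these 6 samples is not settled. Any pairing would rest on these correlations, as the labels do not say what a number marks. The fit with the replicate number as a block is an alternative to both comparisons.

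Of 25 gene lists fixed in advance, 19 had at least 5 tested members. These were tested with camera (limma) at a preset correlation of 0.01, adjusted over the 19 lists, and again with a correlation estimated per list and with fry. The other lists were the mitochondrially encoded mRNAs, the genes raised in eosinophilic esophagitis, and markers of fibroblasts, leukocytes, endothelium and columnar epithelium. Some lists share members, so their calls are not independent. The genes lowered in eosinophilic esophagitis overlap the squamous and junction lists. HIF targets overlap the dioxygenase list, and amino acid stress genes overlap the NRF2 list. Genes named from the lists were chosen by a rule fixed in advance. It takes the 8 largest increases and the 8 largest decreases with an adjusted p under 0.05, a mean of at least 1 RPM and no overlap between the groups. From each list it takes up to 4 called members with the largest change, at least 1 of them from the less common direction, or up to 2 of the most abundant members where none was called. It always takes HIF1A, EPAS1, ARNT, VHL, HIF1AN and EGLN1 to EGLN3, and never clone or locus names, genes of the Y chromosome or XIST. No gene passed over 8 libraries, so the rule was applied to the 6-library comparison, with no overlap over 3 against 3, a change made after seeing the data. Some genes that the rule selects are not reported here. Where a gene was named outside the rule, the text says so.

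The calculation was tested on simulated data with 1.5-, 2- and 4-fold changes. They were made from the means and dispersions of the vehicle libraries and the real library sizes. The spread of the DMOG libraries did not enter, and far fewer genes were changed than were called over the 6 libraries. The shares recovered need therefore not hold for the real data. With 4 against 4 libraries (11194 genes) it recovered 68.8%, 96.8% and 100% of the changed genes of these sizes. With 3 against 3 (11177 genes) it recovered 61.2%, 87.5% and 100%. With 4 against 4 and 1 treated library left unchanged (11187 genes), it recovered 0 of 67, 2 of 66 and 0 of 66. Unchanged genes were called 11, 9 and 1 times in these tests. A list shifted by 0.5 (log2) was called by camera in each of the 3 tests, and 0 of the 18 other lists was called. The simulated genes were drawn independently of one another, so this does not show how camera behaves when genes of a list are correlated.

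Alternatives were median-ratio, upper-quartile and TMM factors (30% of M and 5% of A values trimmed), limma-voom on recovered reads, no filter, a filter of 1 RPM in 4 libraries, a pseudocount of 0.1, non-robust variances, the replicate block, vehicle replicate 2 added to the 6 libraries, and each library left out in turn. Reading and figures used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9. A GRCh38 annotation served for gene names and GC content only.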

Results

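RNA sequencing was done on air-liquid interface cultures of EPC2-hTERT cells, which stratify as the esophageal lining does. There were 2 groups of 4 libraries, cultures given DMSO vehicle and cultures given 1 mM DMOG for 18 h. DMOG is a cell-permeable analog of 2-oxoglutarate that blocks prolyl hydroxylases, the enzymes that mark hypoxia-inducible factor (HIF) alpha subunits for degradation. The comparison asked how expression changes when these enzymes are blocked in esophageal epithelium, against a background of interest in HIF-1α and the differentiation defects of eosinophilic esophagitis. Vehicle replicates 1 to 4 had 32707991, 34784359, 39931833 and 34068135 reads in genes, and DMOG replicates 1 to 4 had 33489545, 34171313, 32334970 and 31245695. Between 10558 and 11242 genes per library had an RPKM of 1 or more.

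Over all 8 libraries, genes that HIF induces and genes of glycolysis stood higher with DMOG than other genes, and genes of the ATF4 amino acid stress response and of oxidative phosphorylation stood lower. The median log2 fold change was 0.76 over 34 HIF targets outside glycolysis (camera adjusted p = 7.46e-13) and 0.94 over 22 glycolysis genes (3.42e-14). It was -1.73 over 21 amino acid stress genes (0.00452) and -0.38 over 64 nuclear subunits of oxidative phosphorylation (9.61e-09). With an estimated correlation, adjusted p = 0.299, 0.299, 0.676 and 0.676 for these lists. Fry, which tests whether the genes of a list move on balance one way, gave 0.212, 0.147, 0.147 and 0.116. It called the last 3 of them without DMOG replicate 2 (0.0151, 0.00441 and 0.00441), and oxidative phosphorylation with upper-quartile factors (0.0436). No single gene passed, although CA9, a carbonic anhydrase induced by HIF-1, had 0.734 ± 0.496 RPKM with vehicle and 23.8 ± 24.4 with DMOG (SD, n = 4 each, log2 fold change 3.22 ± 0.72 SE, limma adjusted p = 0.0879). PSAT1, an enzyme of serine synthesis, had 243 ± 73.0 RPKM with vehicle and 65.7 ± 107 with DMOG (n = 4 each, log2 fold change -3.31 ± 0.96, adjusted p = 0.0879).

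Across the 11122 genes tested in 8 libraries, limma-trend called 0 genes higher and 0 lower, with 665 higher and 3243 lower at an unadjusted p under 0.05. With median-ratio factors it also called 0 and 0 (1556 and 1813 unadjusted), as did limma-voom on the recovered reads. Those factors moved the median log2 fold change from -0.18 to 0.00. Of the genes scaled by them, 560 had all 4 DMOG libraries above all 4 vehicle libraries and 815 had them below. Chance gives 159 each way, or 2.86% of genes in both directions together, if all 8 libraries are alike. An excess over this can come from DMOG replicates 1, 3 and 4 alone, so it does not show a change in DMOG replicate 2. Adjusted over the list alone, 10 HIF targets were higher and 1 lower, 12 glycolysis genes were higher and 0 lower, 1 amino acid stress gene was higher and 15 lower, and 44 oxidative phosphorylation genes were lower, while 0 members of these lists passed over all genes. Camera called 7 lists higher and 3 lower. The other calls were higher genes of squamous differentiation (adjusted p = 0.00138, median 0.08), basal cells (0.000777, median 0.29), junctions (0.00287, median 0.04), genes lowered in eosinophilic esophagitis (0.00287, median 0.17) and ribosomal proteins (0.0487, median -0.00), and lower genes of the endoplasmic reticulum (ER) unfolded protein response (0.0487, median -0.41). Camera compares a list with the other genes, and the median over all genes was -0.18. A list called higher need therefore not have risen. With an estimated correlation the adjusted p = 0.676, 0.299, 0.299, 0.299, 0.767 and 0.676 in that order, and 0 lists were called. The squamous call was lost without DMOG replicate 3 (0.0606), and the ER call without vehicle replicates 2 (0.14) and 3 (0.0702) and DMOG replicates 1 (0.0755) and 4 (0.174). The ribosomal call was lost without vehicle replicates 3 (0.214) and 4 (0.0586) and DMOG replicates 1 (0.174), 2 (0.0757) and 4 (0.174), with no filter (0.194), with the filter of 1 RPM (0.0617) and with the replicate block (0.112). The Notch list (adjusted p = 0.0671) was called higher without vehicle replicate 4 (0.0302), DMOG replicate 1 (0.0211) or DMOG replicate 3 (0.0363). Dioxygenase genes (0.0671, median -0.03, fry direction lower) were called higher with median-ratio (0.037), upper-quartile (0.0347) and TMM factors (0.0376) and without vehicle replicate 4 (0.0364), DMOG replicate 1 (0.0322) or DMOG replicate 2 (0.0442). NRF2 genes (0.106) were called lower without vehicle replicate 2 (0.0293) and with no filter (0.0287). Tricarboxylic acid cycle genes (0.106) were called lower with no filter (0.01).

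The library of DMOG replicate 2 lay nearer to the vehicle libraries than to the other DMOG libraries. CA9 stood at 2.56 RPKM in it against 0.129 to 1.29 in the 4 vehicle libraries, ENO2, an enolase isoform, at 1.93 against 0.795 to 1.91, and ASNS, asparagine synthetase, at 152 against 105 to 194. Over the 56 HIF target and glycolysis genes, DMOG replicate 2 lay 0.06 to 0.16 (median, log2) above the individual vehicle libraries. The corresponding ranges were 1.22 to 1.45 for DMOG replicate 1, 0.54 to 0.77 for replicate 3 and 1.97 to 2.11 for replicate 4, and the largest difference between vehicle libraries was 0.13. On the first principal component, with 65.5% of the variance, it lay at -17.1, beside the vehicle libraries (-23.4 to -21.2) and apart from the other DMOG libraries (14.9 to 56.3). Without it, 747 genes were higher and 3585 lower, 168 and 709 of them at least 2-fold, and leaving out any other library gave 0 and 0. The depth of DMOG replicate 2, 34171313 reads, lay within the range of the others.

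**Figure D1:**
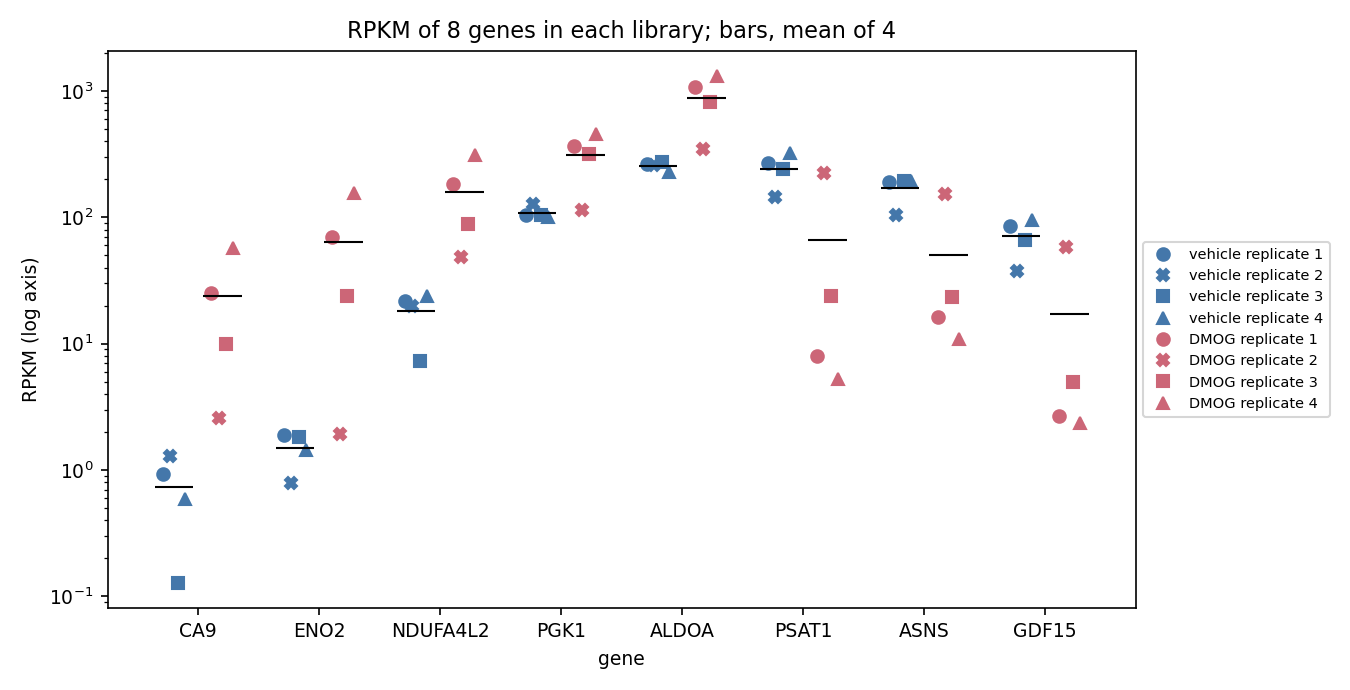
RPKM (log axis) of CA9, ENO2, NDUFA4L2, PGK1, ALDOA, PSAT1, ASNS and GDF15 in each vehicle and DMOG library, with a bar at the mean of the 4 libraries of a group. At CA9, DMOG replicate 2 had 2.56 RPKM, above the vehicle libraries (0.129 to 1.29) and below the other DMOG libraries (9.97 to 57.5).

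**Figure D2:**
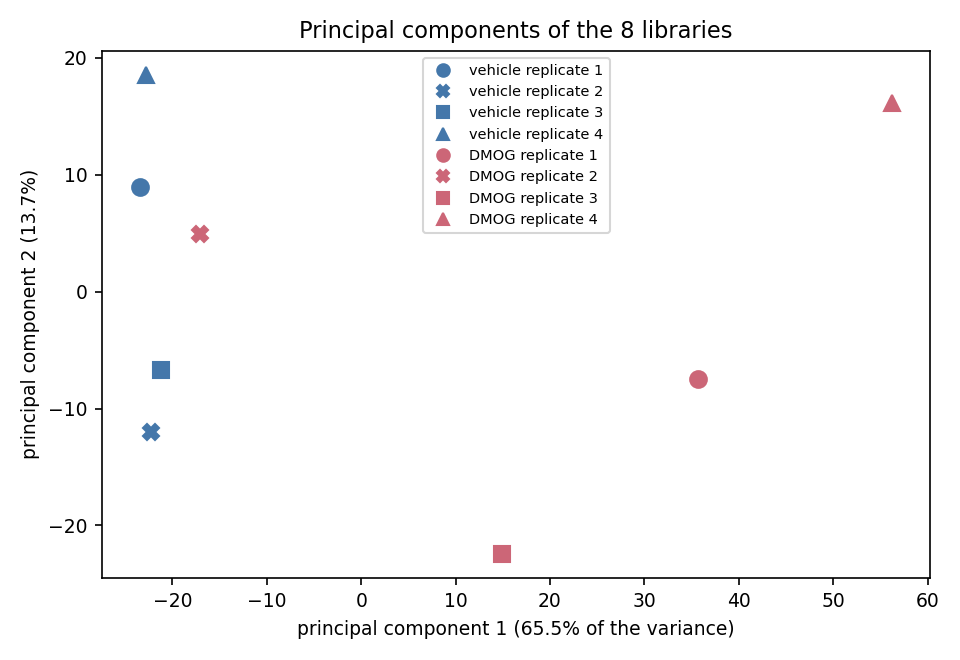
First and second principal components of the 8 libraries, with 65.5% and 13.7% of the variance. DMOG replicate 2 lies at -17.1 on the first component and the vehicle libraries at -23.4 to -21.2.

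In the 6 libraries of the authors' own comparison (replicates 1, 3 and 4 of each group), the genes called higher with DMOG included 19 of 34 HIF targets outside glycolysis and 17 of 22 glycolysis genes, and those called lower 15 of 21 genes of the ATF4 amino acid stress response. The 8 largest increases were those of ENO2, CA9, SLAMF9, a SLAM family receptor, IGFBP3, a binding protein of insulin-like growth factors, EGLN3, a HIF prolyl hydroxylase, NDUFA4L2, a HIF-1 target in mitochondria, ADSSL1, an adenylosuccinate synthase, and HK2, a hexokinase. SLAMF9 (chromosome 1, 159921282 to 159924044) rose from 2.23 ± 1.17 to 42.1 ± 9.19 RPKM (SD, n = 3 each, log2 fold change 4.03 ± 0.28, adjusted p = 0.00182). The 8 largest decreases were those of PSAT1, GDF15, a secreted stress-response factor, PCK2, the mitochondrial PEP carboxykinase, FAM129A, ALDH1L2, a mitochondrial folate enzyme, STC2, a secreted glycoprotein, MOCOS, a molybdenum cofactor sulfurase, and ASNS. Log2 fold changes of these genes ran from 3.26 for HK2 to 4.83 for ENO2 among the increases and from -4.34 for PSAT1 to -3.20 for ASNS among the decreases. The filter kept genes at 1 RPKM or more only in DMOG replicates 1, 3 and 4 out of this ranking. Without vehicle replicate 1, vehicle replicate 4 or DMOG replicate 1 the calls were lost for IGFBP3 (adjusted p = 0.054, 0.0521 and 0.054), EGLN3 (0.0616, 0.0536 and 0.0586) and HK2 (0.0789, 0.0753 and 0.0645), and for HK2 also without vehicle replicate 3 (0.0514) and with no filter (0.057).

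With median-ratio factors, 1526 genes were higher and 1792 lower over the 6 libraries (46.0% of calls higher), of which 331 and 335 changed at least 2-fold. With these factors and no filter, 1166 were higher and 1431 lower. With RPKM as deposited, 682 were higher and 3836 lower (15.1% higher), 175 and 807 at least 2-fold. The median gene was then at -0.26, and the changes given here are relative to it, from the median-ratio fit. Called under both scalings were 682 genes higher and 1792 lower, and 0 in opposite directions. The counts fell to 379 and 539 without vehicle replicate 1, 864 and 1018 without vehicle replicate 3, 466 and 587 without vehicle replicate 4, and 486 and 607 without DMOG replicate 1. Genes at least 2-fold higher numbered 203, 216 and 214 without vehicle replicate 1, vehicle replicate 4 and DMOG replicate 1, and genes at least 2-fold higher and lower 517 and 600 without DMOG replicate 3.

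Of 34 measured HIF targets outside glycolysis 19 were higher, 1 was lower and 14 did not pass (22 and 1 adjusted over the list alone, median log2 fold change 1.28). CA9 (chromosome 9, 35673915 to 35681154) rose from 0.546 ± 0.399 RPKM with vehicle to 30.9 ± 24.3 with DMOG (SD, n = 3 each), a log2 fold change of 4.28 ± 0.58 (adjusted p = 0.00602). NDUFA4L2 (chromosome 12, 57628686 to 57634475) rose from 17.6 ± 9.07 to 194 ± 112 RPKM (3.65 ± 0.57, adjusted p = 0.00794). The member that fell was STC2, from 31.9 ± 12.1 to 2.01 ± 1.69 RPKM (-3.28 ± 0.43, adjusted p = 0.00535). Outside the naming rule and chosen after their values were seen, VEGFA, the vascular growth factor, had a log2 fold change of 0.21 (adjusted p = 0.721, but -0.09 as deposited), ADM, adrenomedullin, 0.54 (0.485) and DDIT4, an inhibitor of mTORC1 signalling, -0.13 (0.863). The camera test of the list gave an adjusted p of 1.34e-06, and adjusted p = 0.547 with an estimated correlation. Fry did not call it (adjusted p = 0.0783), except with vehicle replicate 2 added (0.032) and without DMOG replicate 3 (0.0284). Members called higher fell to 8, 12, 9 and 7 without vehicle replicates 1, 3 and 4 and DMOG replicate 1, and 2 were lower without DMOG replicate 3 or with the replicate block.

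Of 22 glycolysis and lactate genes 17 were higher and 0 lower (20 and 1 adjusted over the list alone, median 1.54). ENO2 (chromosome 12, 7023614 to 7032859) rose from 1.73 ± 0.240 to 83.6 ± 67.6 RPKM (SD, n = 3 each, log2 fold change 4.83 ± 0.62, adjusted p = 0.00535). ALDOA, an aldolase, rose from 255 ± 23.6 to 1067 ± 246 RPKM (2.34 ± 0.22, adjusted p = 0.00282), and PGK1, phosphoglycerate kinase, from 103 ± 1.47 to 379 ± 70.3 RPKM (2.16 ± 0.17, adjusted p = 0.0023). Camera gave an adjusted p of 1.88e-08, and adjusted p = 0.541 with an estimated correlation. Fry gave 0.0329, a call lost with the replicate block (0.0911) and without vehicle replicates 1 (0.0897), 3 (0.103) and 4 (0.099) or DMOG replicates 1 (0.1) and 4 (0.051). Members called higher fell to 9, 9 and 10 without vehicle replicates 1 and 4 and DMOG replicate 1, and 1 was lower without vehicle replicate 3 or DMOG replicate 3 and with RPKM as deposited.

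Of 21 genes of the ATF4 amino acid stress response 15 were lower and 1 higher (the same numbers adjusted over the list alone, median -2.01). PSAT1 (chromosome 9, 80911991 to 80945009) fell from 276 ± 40.8 to 12.4 ± 10.1 RPKM (SD, n = 3 each, log2 fold change -4.34 ± 0.45, adjusted p = 0.00364) and ASNS from 192 ± 3.07 to 16.9 ± 6.38 RPKM (-3.20 ± 0.22, adjusted p = 0.00182). GDF15 (chromosome 19, 18496968 to 18499986) fell from 82.3 ± 14.3 to 3.33 ± 1.41 RPKM (-4.03 ± 0.22, adjusted p = 0.00091). Outside the list, PCK2 (chromosome 14, 24563340 to 24573341) fell from 94.2 ± 11.8 to 5.80 ± 3.54 RPKM (-3.65 ± 0.31, adjusted p = 0.00241) and ALDH1L2 from 27.9 ± 5.27 to 1.45 ± 0.81 RPKM (-3.37 ± 0.24, adjusted p = 0.00186). The member that rose was VLDLR, a lipoprotein receptor (0.99, adjusted p = 0.033), whose call was lost with RPKM as deposited (0.053), with no filter (0.0734) and without vehicle replicates 1 (0.104), 3 (0.0847) and 4 (0.0883) or DMOG replicate 1 (0.0782). Camera gave an adjusted p of 4.73e-07, and adjusted p = 0.541 with an estimated correlation. Fry gave 0.0133, a call lost with the replicate block (0.0682) and without vehicle replicate 1 (0.0526) or DMOG replicates 1 (0.0877) and 4 (0.051).

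Of 64 nuclear subunits of oxidative phosphorylation, 19 were lower and 0 higher (the same adjusted over the list alone, median -0.21), and with RPKM as deposited 52 were lower (median -0.50). NDUFB9 (chromosome 8, 125551343 to 125562227), a subunit of complex I, fell from 75.9 ± 6.76 to 27.7 ± 3.49 RPKM (SD, n = 3 each, log2 fold change -1.13 ± 0.14, adjusted p = 0.00474), and NDUFB2 and NDUFA7, also of complex I, changed by -0.71 ± 0.10 (adjusted p = 0.00629) and -0.64 ± 0.09 (0.00654). Camera gave the list an adjusted p of 2.19e-05, and adjusted p = 0.541 with an estimated correlation. Only the 55 subunits with a GC value (median -0.21) could be matched on length, GC content and expression. Lists matched to them had a median as low in 9.84% of 10000 draws. Fry gave 0.0292, a call lost without vehicle replicates 1 (0.0526), 3 (0.0596) and 4 (0.0695) or DMOG replicates 1 (0.1) and 4 (0.0542). Without vehicle replicates 1, 3 and 4 and DMOG replicate 1, 4, 9, 4 and 3 subunits were lower, and 1 was higher without DMOG replicate 3. Of 22 tricarboxylic acid cycle genes 4 were higher and 6 lower (4 and 7 adjusted over the list alone, median -0.16, camera adjusted p = 0.283, and adjusted p = 0.632 with an estimated correlation, fry 0.194, but 0.0118 as deposited). IDH2, the mitochondrial NADP isocitrate dehydrogenase, rose by 1.3 ± 0.15 (adjusted p = 0.00428) and SUCLG1, a subunit of succinyl-CoA ligase, by 1.11 ± 0.11 (0.00318). Of 18 fatty acid oxidation genes 3 were higher and 5 lower (4 and 5 adjusted over the list alone, median -0.18, camera adjusted p = 0.181, and adjusted p = 0.547 with an estimated correlation). Fry gave 0.0329, a call lost with upper-quartile factors (0.0504) and without vehicle replicates 1 (0.0526) and 3 (0.0642) or DMOG replicates 1 (0.1), 3 (0.0591) and 4 (0.0542). ECI1, an enoyl-CoA isomerase, fell by 1.20 ± 0.13 (adjusted p = 0.00409), and CPT1A, the carnitine palmitoyltransferase of the outer mitochondrial membrane, fell by 1.04 ± 0.17 (0.00836). With RPKM as deposited 2 cycle genes were higher and 15 lower, and 0 oxidation genes were higher and 11 lower. Cycle genes called were 2 higher and 0 lower without vehicle replicate 1, 3 or 4, and 2 and 1 without DMOG replicate 1. Oxidation genes called were 0 higher and 3 lower without vehicle replicate 1, vehicle replicate 4 or DMOG replicate 1, and 0 and 5 without vehicle replicate 3.

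Of 34 squamous differentiation genes 8 were higher and 1 lower (the same adjusted over the list alone, median 0.35, as deposited 0.05). FLG (chromosome 1, 152274651 to 152297679), which encodes filaggrin of the cornified layer, rose from 2.80 ± 1.95 to 11 ± 3.52 RPKM (SD, n = 3 each, log2 fold change 1.97 ± 0.36, adjusted p = 0.0111), and CALML5, a calmodulin-like protein of differentiating keratinocytes, rose by 1.77 ± 0.29 (0.0089). TGM3, a transglutaminase, fell by 0.92 (adjusted p = 0.0163, but 0.0572 and 0.0594 without vehicle replicates 1 and 4). Of 27 junction and desmosome genes 9 were higher and 1 lower (10 and 1 adjusted over the list alone, median 0.33, as deposited 0.05). DSC2 (chromosome 18, 28645942 to 28682388), a desmosomal cadherin, rose from 196 ± 19.2 to 397 ± 31.5 RPKM (1.32 ± 0.13, adjusted p = 0.00318), and PKP2, a desmosomal plaque protein, rose by 1.15 ± 0.18 (0.00836). Of 20 basal cell genes 8 were higher and 0 lower (10 and 2 adjusted over the list alone, median 0.63, as deposited 0.33). The basal gene PDPN, which encodes podoplanin, a membrane glycoprotein, rose by 1.33 (adjusted p = 0.0207, but 0.0576, 0.0695 and 0.0779 without vehicle replicate 1, vehicle replicate 4 and DMOG replicate 1, 0.0513 with no filter and 0.0693 with vehicle replicate 2 added). Camera adjusted p-values were 0.0115 for the squamous, 0.00211 for the junction and 0.0099 for the basal list, and adjusted p = 0.632, 0.541 and 0.541 with an estimated correlation. Without DMOG replicate 3 the squamous list gave 0.192. Its median was 0.17 without DMOG replicate 3 and 0.18 without vehicle replicate 1. Relative to the vehicle mean of the 8 libraries it lay at 0.69 in DMOG replicate 3 and at 0.18 and 0.17 in DMOG replicates 1 and 4, against 0.11 in vehicle replicate 4. Fry gave 0.194 for the squamous, 0.0329 for the junction and 0.0329 for the basal list. The junction call was lost as deposited (0.238), with the replicate block (0.0682) and without vehicle replicates 1 (0.161) and 4 (0.108) or DMOG replicates 1 (0.105), 3 (0.0669) and 4 (0.0797). The basal call was lost as deposited (0.31), with the block (0.0682), with vehicle replicate 2 added (0.123) and without vehicle replicates 1 (0.0526), 3 (0.103) and 4 (0.099) or DMOG replicates 1 (0.105) and 4 (0.112). Members called higher in the squamous list numbered 3, 4 and 4, and in the junction list 3, 5 and 4, without vehicle replicate 1, vehicle replicate 4 and DMOG replicate 1. In the basal list they numbered 1, 3, 1, 1 and 5 without vehicle replicates 1, 3 and 4 and DMOG replicates 1 and 4, and with the replicate block 14 squamous genes were higher. With RPKM as deposited 4 basal genes were higher and 3 lower, and 6 junction genes were higher.

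Genes that are lowered in eosinophilic esophagitis were higher with DMOG in 5 of 13 cases and lower in 0 (the same adjusted over the list alone, median 0.41, but 0.12 with 4 higher as deposited). Besides FLG, which is also in the squamous list, ENDOU, an endoribonuclease, rose by 1.42 ± 0.19 (log2, adjusted p = 0.00599) and GRK5, a kinase of G protein-coupled receptors, by 0.86 ± 0.11 (0.00535). Camera gave an adjusted p of 0.0115, and adjusted p = 0.541 with an estimated correlation, and 0.053 without DMOG replicate 3. The median was 0.64 without DMOG replicate 4. Fry gave 0.0329, a call lost as deposited (0.217), with the replicate block (0.0793) and without vehicle replicates 1 (0.0897) and 3 (0.103) or DMOG replicates 1 (0.1), 3 (0.0591) and 4 (0.0542). Without vehicle replicate 1, 3 or 4 or DMOG replicate 1, 3 members were higher. Of 4 measured genes that are raised in the disease 1 was higher (also 1 adjusted over the list alone), SYNPO, which encodes an actin-binding protein, at 0.73 (adjusted p = 0.0422). Its call was lost with RPKM as deposited (0.125), with no filter (0.0847) and without vehicle replicates 1 (0.0603), 3 (0.116) and 4 (0.111) or DMOG replicates 1 (0.129) and 4 (0.0888).

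**Figure D3:**
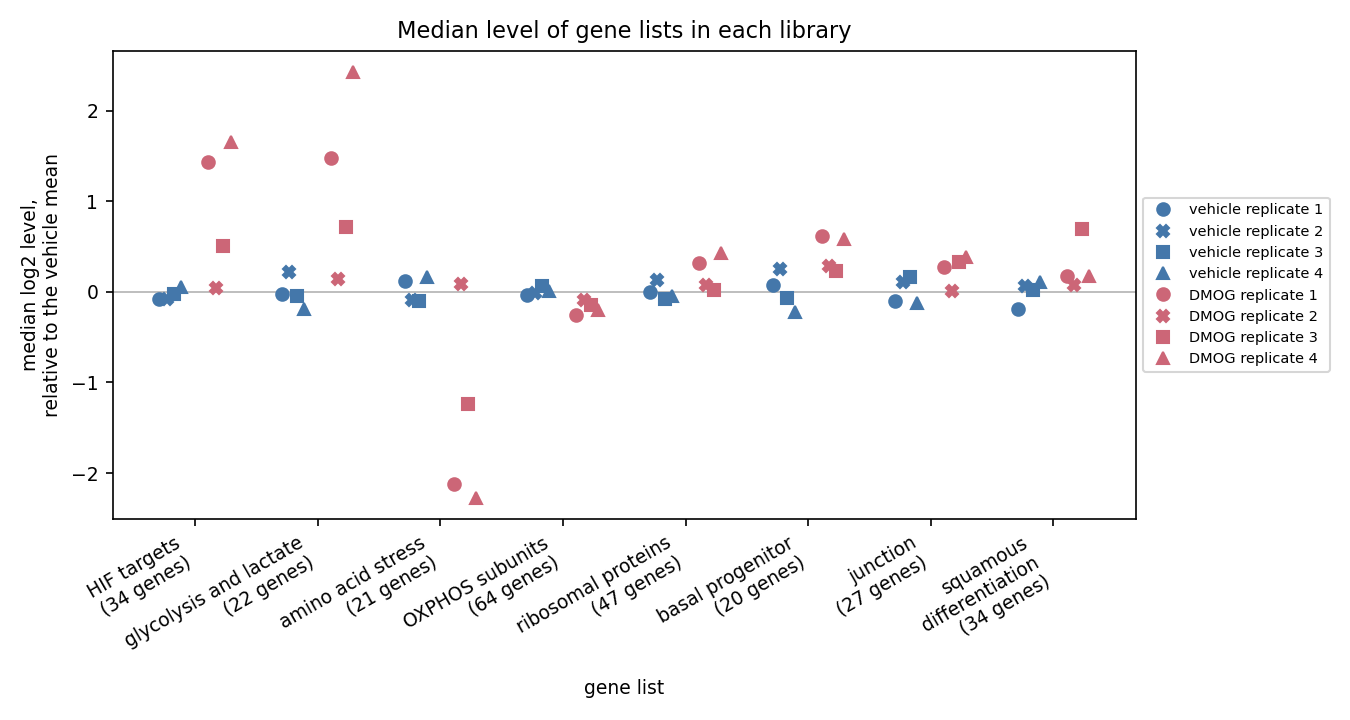
Median log2 level of 8 gene lists in each library, relative to the vehicle mean, with a point for each vehicle and DMOG library. HIF targets lie at 1.44, 0.04, 0.51 and 1.66 in DMOG replicates 1 to 4, and amino acid stress genes at -2.12, 0.08, -1.24 and -2.27.

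The NRF2, ER, interferon and cytokine lists did not pass camera over the 6 libraries, while fry called the NRF2 list lower (adjusted p = 0.0329, and 0.3, 0.194 and 0.427 for the others). That call was lost with vehicle replicate 2 added (0.137) and without vehicle replicates 1 (0.0526), 3 (0.103) and 4 (0.099) or DMOG replicates 1 (0.105) and 4 (0.0797). Fry called the ER list without DMOG replicate 3 (0.0296) and the interferon list with the replicate block (0.00583). Of 20 NRF2 antioxidant genes 2 were higher and 6 lower (the same adjusted over the list alone, median -0.34), with changes of -1.0 ± 0.17 for NQO1, a quinone reductase (adjusted p = 0.00935), and of -0.81 ± 0.10 for GCLC, of glutathione synthesis (0.00535). The camera adjusted p was 0.0623, and adjusted p = 0.541 with an estimated correlation. The list was called lower with the replicate block (0.0231), with no filter (0.0283), with the filter of 1 RPM (0.0498) and without vehicle replicate 1 (0.0307) or DMOG replicate 4 (0.0424). Of 18 ER unfolded protein response genes 4 were lower (4 adjusted over the list alone, median -0.23, camera adjusted p = 0.0858, and adjusted p = 0.677 with an estimated correlation), among them SEL1L, of ER-associated degradation, which fell by 0.65 ± 0.10 (0.00787). That list was called without DMOG replicate 3 (0.00421) and with vehicle replicate 2 added (0.0384). Of 16 interferon response genes 2 were lower (2 adjusted over the list alone, median -0.15, camera adjusted p = 0.195, and adjusted p = 0.677 with an estimated correlation), and XAF1, an interferon-induced gene, fell by 0.88 ± 0.14 (adjusted p = 0.00836). Of 20 NF-κB targets and cytokines 3 were higher and 4 lower (the same adjusted over the list alone, median -0.21, camera adjusted p = 0.561, and adjusted p = 0.781 with an estimated correlation), and CCL20, a chemokine, fell by 1.23 ± 0.16 (0.00535). Log2 values in the authors' deposited table were larger, at -1.61 for XAF1 and -2.34 for CCL20. The log2(RPKM + 1) scale used here understates changes of genes with low values. Without vehicle replicates 1, 3 and 4 and DMOG replicate 1, the genes called lower were 2, 3, 4 and 2 of the NRF2 list, 1, 1, 1 and 1 of the ER list and 1, 2, 1 and 1 of the cytokine list. Those called higher were 0, 1, 0 and 0 of the NRF2 list and 0, 0, 0 and 1 of the cytokine list. Without DMOG replicate 4, 1 gene was higher in each of the NRF2, ER and interferon lists. The ER median was -0.39 and -0.11 without DMOG replicates 3 and 4. The interferon median was -0.10, -0.10 and -0.26 without vehicle replicates 1, 3 and 4, and the cytokine median -0.04, -0.38 and 0.10 without vehicle replicate 3 and DMOG replicates 3 and 4. The interferon list had 4 lower without DMOG replicate 3 and 5 with the replicate block, and was called with no filter (0.0178). With RPKM as deposited 8 ER genes and 4 interferon genes were lower, 0 NRF2 genes were higher and 8 lower, and 0 cytokine genes were higher and 5 lower. The cytokine list then had a camera direction of higher (adjusted p = 0.98) against a median of -0.50.

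Of 24 cholesterol synthesis genes 6 were higher and 2 lower (the same adjusted over the list alone, median 0.13, but -0.16 with 2 higher and 4 lower as deposited). SQLE, squalene epoxidase, rose by 1.02 ± 0.15 (log2, adjusted p = 0.00654) and NSDHL, a sterol dehydrogenase, by 0.68 ± 0.10 (0.00716). Of 19 chromatin and RNA demethylases and related dioxygenases, enzymes that depend on 2-oxoglutarate, 5 were higher and 0 lower (3 and 0 adjusted over the list alone, median 0.22, but -0.07 with 2 higher and 2 lower as deposited). Camera adjusted p-values were 0.159 and 0.0467, and adjusted p = 0.677 and 0.632 with an estimated correlation. Fry gave 0.189 and 0.131. The cholesterol list was called without DMOG replicate 1 (0.0487), and its median was 0.04 without vehicle replicate 3. The dioxygenase call was lost as deposited (0.0955), with the replicate block (0.0575) and without vehicle replicates 1 (0.0662) and 3 (0.077) or DMOG replicate 4 (0.0917). Cholesterol genes called higher were 2, 3 and 2 without vehicle replicates 1, 3 and 4, and dioxygenase genes called higher 0, 1, 0, 1 and 3 without vehicle replicates 1, 3 and 4 and DMOG replicates 1 and 4. In the cell cycle list 1 of 13 genes was higher and 1 lower (0 and 1 adjusted over the list alone, median 0.03, mean -0.13, camera direction lower, adjusted p = 0.696, and adjusted p = 0.885 with an estimated correlation, fry 0.72). As deposited 0 were higher and 3 lower (median -0.15), and with the replicate block 2 and 3. With 1 of the 6 libraries left out the median lay between -0.12 (vehicle replicate 3) and 0.24 (vehicle replicate 1). With median-ratio factors the lower gene was PCNA, the sliding clamp of DNA replication, which fell from 28.2 ± 3.14 to 10.8 ± 2.94 RPKM (SD, n = 3 each, -1.06 ± 0.18, adjusted p = 0.0089). The higher one, MCM5, a subunit of the replicative helicase, was at 0.53 (adjusted p = 0.0457, but 0.215 as deposited, 0.0811 with no filter and 0.596 with vehicle replicate 2 added). Its adjusted p was 0.0663, 0.0859, 0.115, 0.123, 0.0636 and 0.0648 without vehicle replicates 1, 3 and 4 and DMOG replicates 1, 3 and 4, so 0 were higher in each case, while 2 were lower without vehicle replicate 3 and 3 without DMOG replicate 3. In the Notch list 1 of 15 genes was higher (0 adjusted over the list alone, median 0.30, but 0.03 with 0 higher and 2 lower as deposited, camera adjusted p = 0.269, and adjusted p = 0.677 with an estimated correlation, fry 0.359), MAML1, a coactivator, at 0.30 (adjusted p = 0.0457, but 0.857 as deposited and 0.0523 with TMM factors). Without vehicle replicates 1, 3 and 4 and DMOG replicates 1, 3 and 4, its adjusted p was 0.143, 0.126, 0.146, 0.131, 0.0502 and 0.0546. With 1 of the 6 libraries left out 0 Notch genes were called, except without DMOG replicate 3 (2), and 4 were higher with the replicate block. The Notch median was 0.09 without DMOG replicate 4.

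Of the HIF pathway's own genes, EGLN3 (chromosome 14, 34393421 to 34420284) rose from 9.90 ± 3.98 to 163 ± 154 RPKM (SD, n = 3 each, log2 fold change 3.74 ± 0.78, adjusted p = 0.0152), and HIF1A, encoding HIF-1α, fell by 0.52 ± 0.13 (0.0238). Without vehicle replicate 1, vehicle replicate 4 or DMOG replicate 1, EGLN3 gave 0.0616, 0.0536 and 0.0586, and HIF1A 0.0861, 0.0883 and 0.0909. EGLN2, another HIF prolyl hydroxylase, was higher by 0.40 ± 0.12 (adjusted p = 0.0466), a call lost as deposited (0.234), with no filter (0.0646), a pseudocount of 0.1 (0.0512) or vehicle replicate 2 added (0.0766), and without vehicle replicates 1 (0.0673), 3 (0.131) and 4 (0.159) or DMOG replicates 1 (0.129) and 4 (0.077). EGLN1, the main HIF prolyl hydroxylase in normoxia, was at 0.83 ± 0.31 (adjusted p = 0.0813, 0.0403 with the replicate block, 0.043 with vehicle replicate 2 added and 0.00652 without DMOG replicate 3). ARNT, the beta subunit of HIF, was at 0.54 ± 0.17 (0.0545, 0.0266 with the block, 0.0489 with limma-voom, 0.0275 with vehicle replicate 2 added and 0.00733 without DMOG replicate 3). EPAS1, encoding HIF-2α, was at -0.22 ± 0.15 (0.297), and was called lower as deposited (0.0216) and without DMOG replicate 4 (0.0338). VHL, the ubiquitin ligase subunit that binds HIF alpha, was at 0.06 ± 0.13 (0.729) but -0.21 as deposited, and HIF1AN, the asparagine hydroxylase that inhibits HIF, at -0.04 ± 0.12 (0.817) but 0.0634 with vehicle replicate 2 added.

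Markers of other cell types were mostly below the expression filter. The fibroblast list had 1 measured gene, the collagen gene COL1A1, which rose from 12.7 ± 1.28 to 27.3 ± 4.85 RPKM (SD, n = 3 each, log2 fold change 1.32 ± 0.17, adjusted p = 0.00535). Of 2 leukocyte markers, CD14, a receptor for lipopolysaccharide, fell by 1.05 ± 0.14 (0.00597). It had 1.18 to 2.08 RPKM with vehicle and 0.159 to 0.274 with DMOG in these libraries. The log2(RPKM + 1) scale understates such a fall, and the log2 value in the authors' deposited table was -2.80. CD68, a lysosomal protein, was higher by 0.79 (0.0388), a call lost as deposited (0.117), with no filter (0.08) and without vehicle replicates 1 (0.121) and 4 (0.115) or DMOG replicates 1 (0.109) and 3 (0.0687). Adjusted over the list alone, 1 fibroblast marker was higher and 1 leukocyte marker was higher and 1 lower. The endothelial gene VWF was at -0.17 (0.437). The columnar keratin genes KRT8 and KRT18 were at 0.54 (0.186) and -0.18 (0.29), KRT8 being called without DMOG replicate 3 (0.0435) and KRT18 as deposited (0.019), and 0 endothelial and 0 columnar genes were called, over all genes or adjusted over the list alone. Of 47 ribosomal protein genes 0 passed by limma-trend in the 6 libraries (0 adjusted over the list alone, 12 higher at an unadjusted p under 0.05), and 36 were higher without DMOG replicate 3. Their median was 0.29, but -0.01 as deposited, with a camera adjusted p of 2.19e-05, and adjusted p = 0.632 with an estimated correlation, and fry 0.151 (0.0217 without DMOG replicate 3).

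In the authors' deposited table, 2522 of 13424 genes were higher and 2362 lower at their adjusted p under 0.05, 871 and 848 of them at least 2-fold. Of the 11004 genes in both comparisons, 1518 were higher in both and 1762 lower in both, where independent lists of these sizes would share 299 and 342. Of 3300 calls here, 3280 (99.4%) were made in the same direction in the authors' deposited table and 0 in the opposite direction. These comparisons use the same 6 libraries, so the shared calls are not independent evidence.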

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

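Of the tests reported here, the exchange of labels, the comparison of DMOG replicate 2 with vehicle libraries other than replicate 2, the length test and the test of short transcripts were chosen after their results were seen, as were the 6-library comparison and the spreads with 1 library left out.

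Of 278 sets of 4 values, 16 had 1 library far from the other 3 by Dixon's test, and chance gives about 5% of sets. Values are log2(RPKM + 1) unless stated, with the range of the other 3 libraries of the group. In DMOG replicate 2, CD14 stood at 1.18 (0.21 to 0.35), FAM129A at 5.44 (1.88 to 2.40), PKP2 at 3.90 (4.65 to 4.79) and SUCLG1 at 5.15 (5.85 to 5.94). In vehicle replicate 2, ASNS stood at 6.73 (7.57 to 7.61), GCLC at 3.45 (3.78 to 3.82), PGK1 at 6.995 (6.68 to 6.72) and STAT2 at 3.19 (3.72 to 3.77), and the 100 most abundant genes took 30.5% of reads (26.3 to 26.7). In vehicle replicate 3, GRK5 stood at 2.58 (2.80 to 2.83), NDUFA4L2 at 3.04 (4.38 to 4.64) and RPS2 at 10.61 (11.001 to 11.08), and RPS2 stood at 10.28 (10.98 to 11.03) in DMOG replicate 3. FLG stood at 2.60 in vehicle replicate 4 (1.39 to 1.49). The median level relative to the vehicle mean was 0.69 for squamous genes in DMOG replicate 3 (0.08 to 0.18) and 0.61 for Notch genes in DMOG replicate 4 (0.04 to 0.12).

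DMOG replicate 2 stood near the vehicle libraries. Vehicle replicate 2 lay at 0.107 (interquartile range 0.527) over the 3318 called genes, on a scale of 0 at the vehicle mean and 1 at the DMOG mean, against 0.125 for DMOG replicate 2 itself. This argues against an exchange of these 2 labels in which the treated culture responded as the other DMOG cultures did. Since both libraries lay at the vehicle end, the position cannot detect an exchange if neither culture responded, or if the treated one responded weakly. A culture that received no DMOG, or a vehicle library under a DMOG label, stays open. For it, HIF and glycolysis genes differed between the replicate 2 libraries by 0.0582 (median, log2), within the 0.13 between vehicle libraries, and the library most like DMOG replicate 2 by the chi-square statistic was vehicle replicate 1, at 20.7 against at least 36.4 between vehicle libraries. Against it, DMOG replicate 2 lay above each of the 4 vehicle libraries in these genes, by 0.156 over vehicle replicate 4, and CA9 stood at 2.56 RPKM in it and at 0.129 to 1.29 in them. A mixture was to be ruled out if intervals of the treated share from raised and lowered genes did not overlap. They did not (-0.827%, from -2.37 to 0.595, and 6.55%, from 4.27 to 8.72). But that bound left out spread between libraries, since pairs of vehicle libraries gave -7.79 to 14.1%, so a small treated share stays open. The highest of these pairs held vehicle replicate 2, which lay at 4.76 to 14.1% over the other vehicle libraries. Pairs without it gave up to 10.3%. A weak response in vehicle replicate 2 under an exchanged label therefore stays open as well. A culture that took DMOG and did not respond was not tested.

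The labels gave 0 calls over the 8 libraries, so all 35 of the 35 splits gave at least as many by construction, which says nothing about chance. The highest other split, with 1197 calls (129 and 1068, or 61 and 89 with median-ratio factors), exchanges the labels of the replicate 2 libraries and points to a structure of the samples. Over the 6 libraries, 1 of 10 splits, the labels' own with 3318 calls, gave as many, and the highest other gave 0. These splits are too few for a share under 0.05, and the same highest value of 0 holds among the 4 splits that part all 3 pairs.

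The median gene had a lower RPKM in the 3 DMOG libraries, by -0.26 (log2). Reads taken by abundant genes account for part but not all of it, as leaving the 100 most abundant genes out of the totals gave -0.15, or 55.4% of the shift (53.4 to 57.8% with 1 library left out), and leaving out 1000 gave -0.07. The longest genes (a class of 20% by rank) shifted by -0.15 and the shortest by -0.38, a ratio of 37.9% (32.1 to 43.4%). A length bias can therefore be part of the shift. Classes of length cannot part it from other causes that act on genes of all lengths, so its share stays open. RPKM shares cannot show a change in total RNA, which stays open and was not tested.

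Of 64 subunits of oxidative phosphorylation 19 were lower in the 3 DMOG libraries (median -0.21). A general loss of short transcripts stays open. Ribosomal protein genes, of like length (median 849 and 861 bases), stood at 0.29 with an interquartile range of 0.103 and so did not share the fall (-0.01 as deposited, where the subunits stood at -0.50), but they are 1 list, and over all genes the shortest shifted by -0.38 and the longest by -0.15 as deposited. The length, GC content and expression of the subunit genes could account for the fall, judged on the 55 subunits with a GC value. Their median (-0.21) lay at percentile 9.84 of 10000 matched lists, whose median was -0.11 and central 95% -0.27 to 0.06. An effect of DMOG on these genes stays open as well.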

How the results depend on the processing

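The 6-library comparison, TMM factors, a pseudocount of 0.1, vehicle replicate 2 added to the 6 libraries, every alternative of the 6-library comparison, and fry under each alternative were added after seeing the data. The planned edgeR quasi-likelihood F test on counts was not run, since the plan named limma-trend for a table without counts. Reads could nevertheless be recovered, and limma-voom was run on them. Over 8 libraries 0 genes were called under every full-library setting. Leaving out 1 library, with RPKM as deposited, gave 0 to 747 higher and 0 to 3585 lower, 0 to 168 and 0 to 709 at least 2-fold. The 6 libraries gave 682 and 3836 (175 and 807 at least 2-fold) as deposited and 1526 and 1792 (331 and 335) with median-ratio factors, DMOG replicate 2 being left out. Lists lower over 8 libraries numbered 5 with no filter, and 0 were called higher or lower with an estimated correlation or fry, but fry called 1 and 2 with upper-quartile factors and 1 and 4 without DMOG replicate 2. Over 6 libraries, genes at least 2-fold lower numbered 647 with limma-voom and 595 with a pseudocount of 0.1, which shrink low genes less. Leaving out 1 library gave 379 to 2224 higher and 539 to 2527 lower, 203 to 517 and 231 to 600 at least 2-fold. Lists lower numbered 4 with no filter, and 0 and 0 lists were called with an estimated correlation. Fry called 4 higher and 4 lower, but 5 and 4 with no filter, 4 and 3 with upper-quartile factors or vehicle replicate 2 added, and 1 and 5 as deposited. It called 0 and 0 without vehicle replicate 1, DMOG replicate 1 or DMOG replicate 4, 1 and 1 without vehicle replicate 3 and 1 and 2 without vehicle replicate 4.

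Over 8 libraries the deviations of same-numbered libraries correlated at 0.07, -0.02, 0.53 and 0.24, so not every pair of the 8 deviates together. DMOG replicate 2 enters these group means, and the values do not show that numbers 1, 3 and 4 are unpaired. The replicate number as a block gave 0 and 0 genes and 6 higher and 3 lower lists, without the ribosomal list (0.112). Over the 6 libraries the block gave 2181 and 2337 genes (360 and 363 at least 2-fold) and 7 and 3 lists, and 1513 and 1770 of the calls made without it were kept. It ended the camera call of the dioxygenase list and the call of FTL (adjusted p = 0.0553), and started those of the NRF2 list, EGLN1 and ARNT. It changed no other camera call of a list, no other call of a gene that the naming rule selects, and no call of a gene named outside it. Fry called 0 lists higher and 4 lower with the block, losing the glycolysis (0.0911), amino acid stress (0.0682), basal (0.0682) and junction (0.0682) lists and the genes lowered in eosinophilic esophagitis (0.0793), and gaining the interferon list (0.00583).

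Among the genes that the naming rule selects, directions turned for 3, none of them called. VHL was at -0.16 over 8 libraries but 0.0323, 0.0532 and 0.0210 with median-ratio, upper-quartile and TMM factors, and 0.0636 in 6 libraries. HIF1AN was at -0.15 but 0.0386, 0.0594 and 0.0273 with those factors. In 6 libraries VHL was at -0.21 as deposited, -0.0012 with vehicle replicate 2 added and -0.0469 to 0.14 with 1 library left out. HIF1AN was at 0.0634 with that library added and -0.11 to 0.0427 with 1 left out. RPS2 was at -0.13 as deposited and -0.00036 to 0.43 with 1 left out. The causes were not tested. Over 6 libraries 1175 values of the genes that the naming rule selects kept direction and side of the threshold, 196 lost and 12 gained a call and 8 turned. At 31245695 to 39931833 reads, a gene listed at 0 could have up to 0.0751 to 0.0960 RPM by counting error alone, and how the calls depend on depth was not tested.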

Other observations

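All gene families described here were tested after seeing the data, as 131 groups of genes with a shared name stem and at least 10 members, and the genes named were chosen after their values were seen. Camera at its preset correlation called 19 of the 131, and with an estimated correlation 0 (lowest adjusted p = 0.732). The 5 families described were picked from the 19.

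Of 48 MRPL genes, for proteins of the large mitochondrial ribosomal subunit, 30 were lower in the 3 DMOG libraries and 1 higher (median log2 fold change -0.43, camera adjusted p = 4.57e-07), and MRPL24 fell by 1.35 ± 0.20 (adjusted p = 0.00713). Of 29 MRPS genes, of the small subunit, 16 were lower (median -0.49, adjusted p = 0.000532). Of 14 TIMM genes, of protein import into mitochondria, 7 were lower (median -0.58, adjusted p = 0.00973), and TIMM44 fell by 1.32 ± 0.16 (0.00458). Of 10 EXOSC genes, of the RNA exosome, 5 were lower (median -0.65, adjusted p = 0.0127), and EXOSC5 fell by 1.43 ± 0.12 (0.0023). Of 11 SEMA genes, for semaphorins, 6 were higher and 0 lower (median 0.44, adjusted p = 0.0148), and SEMA5A rose by 1.77 ± 0.14 (0.0023). None of these 5 camera calls held with an estimated correlation. At the preset correlation they held with RPKM as deposited, with the replicate block and with each of the 6 libraries left out. As deposited the genes lower were 42 of MRPL (median -0.72), 24 of MRPS (-0.77), 12 of TIMM (-0.84) and 8 of EXOSC (-0.89), and 4 SEMA genes were higher (0.27). Without vehicle replicates 1, 3 and 4 and DMOG replicate 1, the lower genes numbered 10, 14, 9 and 9 for MRPL, 4, 7, 3 and 3 for MRPS and 3, 3, 3 and 3 for EXOSC. For TIMM they were 4 without vehicle replicate 1 or DMOG replicate 1 and 11 without DMOG replicate 3, and the TIMM median was -0.38 without DMOG replicate 4. The higher SEMA genes were 1, 2, 1 and 3 without vehicle replicates 1 and 4 and DMOG replicates 1 and 4. No lists matched on length, GC content and expression were drawn for these families. Whether those traits account for the falls was not tested.

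A hypothesis was that the fall of amino acid stress genes extends to cytosolic aminoacyl-tRNA synthetase genes outside the list and spares the mitochondrial ones. Of 14 cytosolic genes 10 were lower and 1 higher (median -1.15), and of 17 mitochondrial genes 6 were lower (median -0.39). The medians differed by -0.75 (-0.98 to -0.68 with 1 library left out, permutation p = 0.00071 over genes, which are not independent). EPRS, for glutamate and proline, fell by 2.37 ± 0.28 (adjusted p = 0.00458) and YARS, for tyrosine, fell by 2.10 ± 0.18 (0.00241), while DARS, for aspartate, was at 0.45 (0.0197, but 0.229 as deposited, and 0.0852, 0.0604, 0.0742 and 0.0717 without vehicle replicates 1, 3 and 4 and DMOG replicate 1). With RPKM as deposited, 11 cytosolic (median -1.43) and 10 mitochondrial genes (median -0.63) were lower and 0 of either kind higher, and directions turned for QARS (0.06 to -0.24), AARS2 (0.16 to -0.09), HARS2 (0.12 to -0.16), RARS2 (0.04 to -0.24) and TARS2 (0.22 to -0.06), none of them called under either scaling. The cytosolic part holds, but the mitochondrial median lay below the -0.3 set beforehand, so a wider fall that may include both kinds stays open. Without vehicle replicates 1 and 4 and DMOG replicate 1, 6, 6 and 6 cytosolic genes were lower, and of the mitochondrial genes 0, 4, 1 and 0 were lower without vehicle replicates 1, 3 and 4 and DMOG replicate 1.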
